A study of Homo sapiens with 4 samples.

How the data were processed

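RNA from 4 xenograft tumour samples labelled DU145 was hybridised to an Affymetrix human 3' expression array, 1 array for each of vehicle, taxotere, NVP-BEZ235 and the combination. The deposited values are probe set intensities on the linear scale, from 1.22 to 84449. Per the submitters' processing notes, they were made with GCRMA in R 2.6.2, a method that corrects background by probe sequence, quantile normalises the arrays together and summarises the probes of a probe set. Its settings, and whether a further scaling followed, are not given in the sources used here. GCRMA pulls unexpressed probe sets to a narrow low range, so that a fold change against such a level can be very large. A level under log2 6 (an intensity of 64) was therefore treated as not firm, and a difference with 1 side under it is given as at least N-fold against log2 6 or as levels. Counts, list medians, correlations and fits use all values as they are. Quantile normalisation also brings the 4 arrays close to 1 distribution, so that a change in the total amount of mRNA cannot be seen. For arrays, their number limits the precision, and 1 array per group gives no estimate of the spread between tumours.

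The deposited intensities were put on the log2 scale without a pseudocount. Of 54675 probe sets, 41097 named 1 gene in the platform annotation used, 1801 named several and 11777 named none, among them 62 control probe sets. Symbols were updated through the gene identifiers of a RefSeq table (GRCh38.p14), which held those of 41043 of the 41097 probe sets and was used for names only. A gene was represented by the probe set with the highest mean of the 19775 genes with a probe set of their own, and 10068 genes at or above log2 6 on at least 1 array were compared. Probe sets that name several genes were not used. Array probe sets of gene families can cross-hybridise, so that the AKR1C, KRT, IFITM, HLA and tubulin genes named are uncertain in this respect.

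With 1 array per group, differences of log2 values were counted by a fixed size of at least 2-fold. The 5 comparisons were each treatment with vehicle and the combination with each single drug. Each drug's difference without and with the other drug was compared across genes, since these pairs share no array. The departure from additivity was the combination minus taxotere minus NVP-BEZ235 plus vehicle. As a secondary description, limma 3.58.1 (R 4.3.3) fitted an additive 2 x 2 model (lmFit and eBayes, Benjamini-Hochberg adjustment). It was tested on simulated data for the taxotere effect with 10068 genes and an error SD of 0.3 per array. It recovered 100% of 100 genes changed by 3 on the log2 scale and 98% of 100 changed by 1.5, and it called 14 unchanged genes. In the data, the departure from additivity, which serves as the error, had an SD of 0.886 across genes. This is larger than 4 arrays with the simulated error would give. The simulated rates therefore need not hold for these arrays, and a lack of calls is not evidence of no effect.

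Before the data were examined, 35 gene lists were fixed for the drugs' targets, their pathways, the tumour's lineage and other cell types. The median difference of each list with at least 5 measured members, 29 in all, was placed among 10000 random lists of the same size matched on mean level in 10 bins, as a description of these arrays. In a simulation without any effect, 4 of 100 random lists of 25 genes lay outside the central 95%. This follows from how the range is built. It does not show how often a list of genes that vary together would lie outside it without an effect. Genes named in the text were chosen by a rule set at the same time. It took, for each comparison with vehicle, the 10 genes with the largest difference in each direction at or above log2 6 on both arrays, at least 2-fold apart, whose other measured probe sets had the same sign, and the 3 in each direction with the highest level on 1 array and under log2 6 on the other. It added up to 4 members of each list, 10 genes in each direction for the differences that share no array, 6 for the departure from additivity, 5 for the limma fit, and 10 genes of interest. One of these 10 had no probe set of its own and is not reported here. Genes named outside the rule are KLK2, KLK4, FOLH1, ACP3, HOXB13, TRPM8, NKX2-1, SFTPB, NAPSA and those of the lists in the closing section, which were chosen after their values were seen.

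Technical spread was described by the other probe sets of each gene and by control probe sets. The ratio of 3' to 5' probe sets of ACTB, which rises as RNA degrades, was 2.11, 1.92, 2.01 and 1.76 in vehicle, taxotere, NVP-BEZ235 and the combination, and that of GAPDH was 0.850, 0.854, 0.864 and 0.915. The 18 hybridisation control probe sets differed from vehicle by a mean of 0.14, 0.25 and 0.54 on the log2 scale, and the 24 labelling controls by 0.09, -0.17 and -0.18. Alternatives set in advance were other levels for the filter (log2 5, log2 8, none), quantile normalisation and median centring, a pseudocount of 32, the mean of all probe sets of a gene, the use of probe sets not marked as shared between transcripts, and eBayes with a trend. Added after the data were seen was the choice of genes and probe sets from the 3 arrays other than NVP-BEZ235. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Genes missing from the annotation used were not analysed here.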

Results

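Gene expression was measured in xenografts labelled as DU145, a cell line established from a human prostate carcinoma, grown in immunodeficient NOD/SCID mice. One tumour group received vehicle, one received taxotere (docetaxel, a drug that stabilises microtubules) at 10 mg/kg intravenously each week, one received NVP-BEZ235, an oral inhibitor of the kinases PI3K and mTOR, at 12.5 mg/kg daily, and one received both drugs. Treatment lasted 4 weeks. Each of the 4 groups was represented by 1 array of 54675 probe sets, so there were no replicates, and the difference between any pair of arrays has no replicate check and carries no p-value. Genes are described as higher or lower on an array, by size alone. The number of arrays, 1 per group, limits the precision of every value below.

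The 4 arrays had similar overall distributions after the authors' normalisation, with median log2 intensities of 2.99 in vehicle, 2.97 in taxotere, 2.99 in NVP-BEZ235 and 2.96 in the combination. A total of 10068 genes reached a log2 intensity of 6 on at least 1 array and were compared. Across these genes the taxotere and combination arrays were the closest pair (Pearson r = 0.983), and the vehicle array correlated with the combination array at 0.970, with the taxotere array at 0.961 and with the NVP-BEZ235 array at 0.931. The NVP-BEZ235 array was the farthest from the rest, with r = 0.892 to taxotere and 0.906 to the combination. These correlations are across genes, which are not independent replicates. A measure of error within the arrays came from genes with several probe sets. Differences from vehicle measured by different probe sets of the same gene varied with an SD of 0.43 (taxotere), 0.45 (NVP-BEZ235) and 0.31 (combination) on the log2 scale. Among genes at least 2-fold apart, 98.2%, 98.0% and 100% of the other probe sets had the same sign in these comparisons. These figures cover measurement on the array and not variation between tumours.

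Some transcripts of lung epithelium were at high level on all 4 arrays. The transcription factor NKX2-1, used as a marker of lung and thyroid epithelium, lay between log2 11.13 (NVP-BEZ235) and 12.10 (taxotere). Surfactant protein B (SFTPB) lay between 10.59 and 14.28 on the same arrays, and the aspartic peptidase NAPSA between 11.24 and 13.14. Of 15 genes with a probe set in the androgen signalling and luminal prostate list, 9 reached log2 6 on some array and 6 on all 4. STEAP1 lay between 10.83 and 12.20, and FKBP5, which many tissues express, between 10.87 and 11.77. The prostate kallikrein KLK3 did not exceed 6.37, and KLK2, KLK4, FOLH1, ACP3, HOXB13 and TRPM8 were under log2 6 on all 4 arrays. Among the lists of cell types other than tumour epithelium, 2 of 18 endothelial genes with a probe set, 4 of 21 macrophage and leukocyte genes, 1 of 18 skeletal muscle genes, 2 of 12 adipocyte genes, 3 of 12 neuroendocrine genes and 0 of 7 erythroid genes reached log2 6 on any array, so no median is given for these lists. The fibroblast and matrix list had 10 such genes of 22. Host cells in these xenografts are of mouse, whereas the array holds human probe sets. These counts, and the medians of the fibroblast and matrix list below, therefore cannot be read as a measure of the host cells of the tumours. Whether mouse RNA added signal to some of the human probe sets was not tested.

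Taxotere against vehicle asked how tumours treated with docetaxel alone differed from untreated tumours. ALDH1A1, a retinaldehyde dehydrogenase also used as a stem cell marker, was at log2 10.98 against 3.52 in vehicle, which is at least 31.6-fold higher when the low side is set to log2 6. The carbonyl reductase CBR3 was 9.46-fold higher (11.66 against 8.42), the aldo-keto reductase AKR1B10 7.82-fold higher (13.22 against 10.25) and the efflux transporter ABCC2 6.24-fold higher (8.82 against 6.18). Among the lower genes, the EGF receptor ligand EREG was 27.8-fold lower (6.43 against 11.23), the hyaluronan-degrading protein CEMIP 15.8-fold lower, the ectonucleotidase NT5E 9.17-fold lower and the receptor tyrosine kinase MET 7.35-fold lower. In all, 344 genes were at least 2-fold higher and 303 at least 2-fold lower, together 6.43% of the genes compared.

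Other genes far higher with taxotere were IGFBP5 (11.3-fold), CEACAM5 (8.59-fold), CRABP2, which carries retinoic acid (6.56-fold), CRIP1 (5.85-fold), TSPAN7 (5.78-fold), the kinase FYN (5.55-fold) and endothelin EDN1 (5.51-fold). Aquaporin AQP4 and the bradykinin receptor BDKRB2 were under log2 6 in vehicle and at least 28.3-fold and 14.6-fold higher with taxotere. On the lower side stood CHI3L1 (12.2-fold), CLMP (11.6-fold), the chemokine CXCL14 (11.2-fold), the WNT antagonist SFRP1 (9.69-fold), TFPI2 (9.23-fold) and STC1 (6.73-fold). FBN1 was at least 7.54-fold lower and the WNT receptor FZD10 at least 6.66-fold lower, and the matrix glycoprotein TNC was at log2 5.61 against 9.46 in vehicle.

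**Figure D1:**
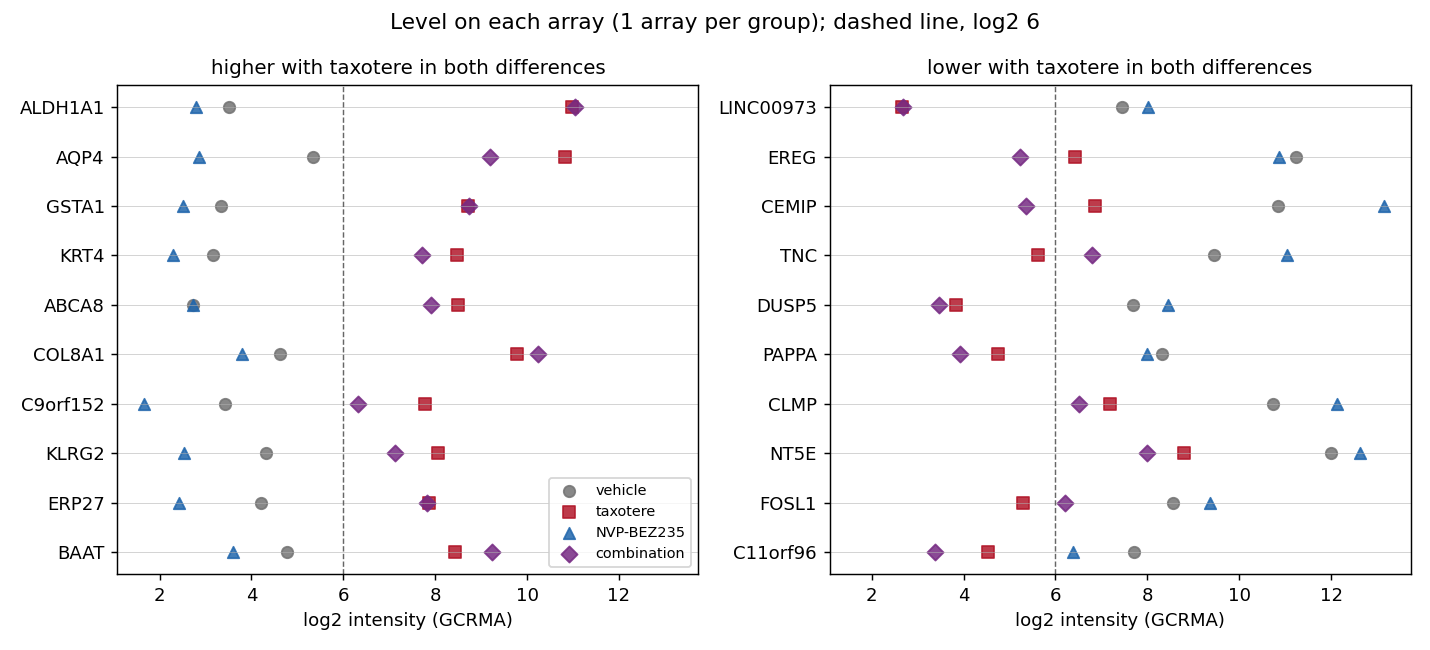
Log2 intensity on each of the 4 arrays (x axis, 1 point per array) of the 10 genes with the largest smaller difference, in each direction, in both taxotere differences that share no array (y axis, gene symbols). ALDH1A1 lies at 10.98 and 11.03 on the taxotere and combination arrays and at 3.52 and 2.80 on the vehicle and NVP-BEZ235 arrays, and the dashed line marks log2 6, below which a level is not firm.

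Of the 29 gene lists fixed in advance that had at least 5 measured members, 12 had a median difference between taxotere and vehicle outside the range that held 95% of random lists of matched level. The p53 and cell cycle arrest list, called cell cycle arrest below, had the lowest median, -0.97 over 23 genes (random lists, -0.14 to 0.18). The short name leaves out p53, and this list does not measure cell cycle arrest alone. Its members DDB2 (-2.02), GADD45A (-1.95), the death receptor FAS (-1.64) and the cyclin-dependent kinase inhibitor CDKN1A (-1.61) were all lower, 9 of the 23 members were at least 2-fold lower and 0 at least 2-fold higher. Immediate early genes had a median of -0.32, with 8 of 25 at least 2-fold lower, among them the MAP kinase phosphatase DUSP5 (at least 3.23-fold), FOSL1 (at least 5.88-fold), ETV5 (at least 5.22-fold) and PHLDA1 (-2.07). Inflammatory and NF-kB genes had a median of -0.55 with 5 of 20 at least 2-fold lower, including LCN2 (-1.73) and CXCL1 (-1.55). The fibroblast and matrix list had a median of -0.66, with 4 of 10 lower by that margin, such as ACTA2 (-1.93) and COL1A1 (-1.68). Its median ran from -0.68 to -0.04 across the settings tried and stayed outside the range of random lists in each. Mesenchymal genes had a median of -0.44, and 7 of 18 were at least 2-fold lower, including PLAU (-2.67) and AXL (-2.10).

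Smaller shifts with taxotere were seen for the interferon response list (median -0.37, 4 of 32 at least 2-fold lower, IFITM3 at -1.14), for PI3K-FOXO feedback genes (-0.37, 2 of 24, FOXO1 at -1.39 and SESN1 at -1.13), for WNT and TGF-beta targets (-0.27) and for apoptosis regulators (-0.18). Higher medians were found for heat shock genes (0.39 over 13 genes, HSPB1 at 1.32), for G2-M and mitosis genes (0.32, 37 of 38 above 0, CCNA2 and ASPM both at 0.89) and for sterol and fatty acid synthesis (0.25 over 20 genes, INSIG1 at 1.21). The medians of the WNT and TGF-beta, apoptosis and sterol lists lay inside the range of random lists under at least 1 alternative setting. Tubulins and microtubule proteins, the targets of docetaxel and their partners, had a median of 0.03 over 25 genes, inside the range of random lists, with MAP2 at 1.96 and MAPRE2 at 1.02. Drug efflux transporters (-0.13), prostate stem and progenitor markers (-0.12), MHC class I (-0.12), autophagy and lysosome (-0.06), oxidative phosphorylation (-0.02), the unfolded protein response (-0.03), ribosome biogenesis (-0.01), ribosomal proteins (0.02), androgen signalling (-0.03), housekeeping genes (0.03), the amino acid and ATF4 response (0.05), G1-S and DNA replication (0.06), glycolysis and hypoxia (0.08), epithelial genes (0.10), keratinised squamous epithelium (0.19) and Notch and Hedgehog genes (0.23) were also inside it. The epithelial and the Notch and Hedgehog lists lay outside it under 1 alternative setting each.

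NVP-BEZ235 against vehicle asked how tumours given the kinase inhibitor alone differed. Fibrinogen beta chain FGB was 79.0-fold lower (log2 7.82 against 14.12), the glutathione peroxidase GPX2 63.8-fold lower (7.05 against 13.04), the interferon-induced oligoadenylate synthetase OAS1 49.1-fold lower (6.79 against 12.41) and the surfactant-associated gene SFTA2 42.8-fold lower (6.66 against 12.08). The tight junction protein CLDN2 was 13.3-fold higher (11.16 against 7.43), the calcium-binding protein S100A8 8.71-fold higher and the WNT receptor FZD4 8.59-fold higher. Counts were 442 genes at least 2-fold higher and 640 at least 2-fold lower, 10.7% of the genes compared.

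Further genes lower with NVP-BEZ235 were S100P (35.8-fold), CHI3L2 (33.3-fold), FGL1 (25.4-fold), IFI27 (21.6-fold), NELL2 (20.2-fold) and IFITM1 (19.5-fold). BPIFA1, a protein secreted by airway epithelium, was under log2 6 with NVP-BEZ235 and at least 78.7-fold lower, CXCL14 at least 69.9-fold and the homeodomain protein HOPX at least 62.4-fold lower. Among the higher genes were GNG4 (7.42-fold), thrombomodulin THBD (6.40-fold), HSPB8 (6.20-fold), TMCC3 (6.17-fold), PLEKHG4 (6.10-fold), ADAM8 (6.06-fold) and RAMP1 (5.85-fold). Carbonic anhydrase CA12, ITPKA and ENPP2, under log2 6 in vehicle, were at least 8.71-fold, 5.71-fold and 5.32-fold higher.

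The interferon response list had the lowest median of the 29 lists on the NVP-BEZ235 array, -1.69 over 32 genes (random lists, -0.14 to 0.23). In it 23 genes were at least 2-fold lower and 0 at least 2-fold higher, and OAS2 was at least 2.65-fold lower. G2-M and mitosis genes had the highest, 1.03 over 38 genes (random lists, -0.11 to 0.21), with 20 at least 2-fold higher and all 38 above 0. BUB1, a spindle checkpoint kinase, was higher by 1.63, CCNA2 by 1.49, CDCA8 by 1.44, and the mitotic kinase PLK1 was at least 2.84-fold higher. G1-S and DNA replication genes had a median of 0.33, with 5 of 33 at least 2-fold higher (ORC6 at 1.39, CDC6 at 1.31). Ribosome biogenesis genes had a median of 0.34 (POLR1A at 1.17, NIP7 at 1.06), heat shock genes 0.36, and tubulins and microtubule proteins 0.25 (MAP2 at 1.67, MAPT at -1.77).

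Lower medians with NVP-BEZ235 included fibroblast and matrix genes (-0.83, 5 of 10 at least 2-fold lower, COL1A1 at -4.48), WNT and TGF-beta targets (-0.80, ID2 at -3.20 and BAMBI at -2.27), androgen signalling and luminal prostate genes (-0.76 over 9 genes, with 2 at least 2-fold higher and 3 lower, STEAP1 at 1.27 and STEAP4 at -2.44), MHC class I (-0.58, HLA-E at -1.45), inflammatory and NF-kB genes (-0.56, with 4 of 20 higher and 4 lower by 2-fold), cell cycle arrest genes (-0.48, CDKN1A at -1.52 but PMAIP1 at 2.02), PI3K-FOXO feedback genes (-0.45, 3 of 24 at least 2-fold lower, KIT at -3.21, PIK3R1 at -1.09 and IRS2 at -0.97), glycolysis and hypoxia genes (-0.44, 9 of 30 at least 2-fold lower, ADM at -2.25 and the glucose transporter SLC2A3 at least 10.4-fold lower) and sterol and fatty acid synthesis (-0.36, SCD at -1.83 and IDI1 at -1.17). Altogether 15 of the 29 lists lay outside the range of random lists. Medians of the fibroblast, androgen, inflammatory, sterol, heat shock and tubulin lists lay inside that range under at least 1 alternative setting. The remaining lists lay inside it: ribosomal proteins (-0.06), Notch and Hedgehog (-0.28), epithelial genes (-0.02), drug efflux transporters (-0.13), prostate stem and progenitor markers (-0.06), the amino acid and ATF4 response (0.01), oxidative phosphorylation (0.09), autophagy and lysosome (0.10), housekeeping (0.12), immediate early genes (0.13), apoptosis regulators (0.13), mesenchymal genes (0.16), the unfolded protein response (0.17) and keratinised squamous epithelium (0.20). Of these, the ribosomal protein, Notch and Hedgehog, drug efflux, mesenchymal and keratinised lists lay outside it under at least 1 alternative setting. Within the epithelial list, 5 of 28 genes were at least 2-fold lower, with the small GTPase RAB25 at least 21.3-fold lower, the transcription factor GRHL2 at least 3.08-fold lower, MUC1 lower by 3.77 (11.02 against 14.79) and the desmosomal protein DSP at -1.68.

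The NVP-BEZ235 array stood apart from each of the other arrays. On it 669 genes were at least 2-fold from every other array, 214 higher and 455 lower, against 65 such genes for the vehicle array, 119 for taxotere and 58 for the combination. By another measure, 29 genes were under log2 4 with NVP-BEZ235 and at or above 7 on the other 3 arrays, and 0 genes met that rule for any other array. RAB25 is one of them, at 2.13 with NVP-BEZ235 against 10.41, 10.66 and 9.58 with vehicle, taxotere and the combination. Each gene group described for NVP-BEZ235 rests on this array.

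**Figure D2:**
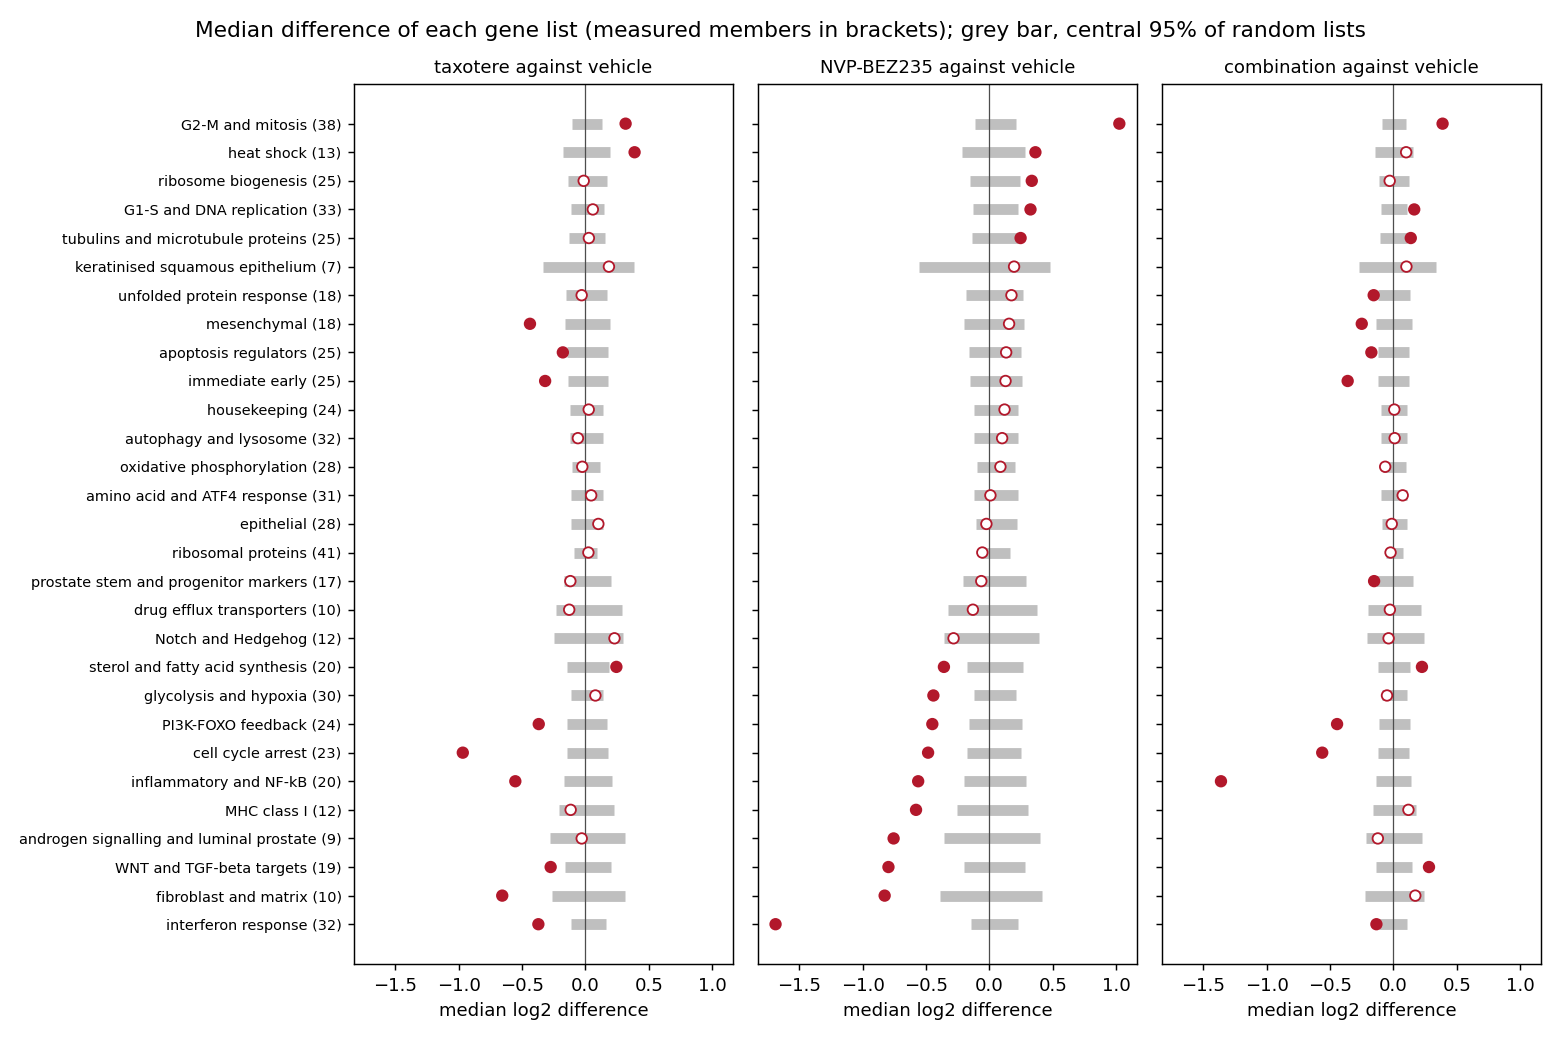
Median log2 difference from vehicle (x axis) of 29 gene lists (y axis, measured members in brackets) for taxotere, NVP-BEZ235 and the combination, with filled circles outside and open circles inside the grey bars that hold the central 95% of 10000 random lists of matched level. G2-M and mitosis genes lie at 0.32, 1.03 and 0.39 in the 3 panels and interferon response genes at -0.37, -1.69 and -0.13.

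The combination against vehicle asked how tumours given both drugs differed. As with taxotere alone, ALDH1A1 was at least 32.8-fold higher (log2 11.03), AKR1B10 9.40-fold higher and CBR3 5.70-fold higher, while EREG was at least 37.5-fold lower and NT5E 16.1-fold lower. Keratin KRT14, a marker of basal epithelium, was at log2 10.12 and at most 5.42 on the other arrays, at least 17.3-fold higher than in vehicle. The chemokine CCL20 was at 5.51 against 10.16 in vehicle, at least 17.9-fold lower. Fewer genes differed than for either drug alone, 234 at least 2-fold higher and 192 lower, or 4.23% of those compared.

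Also higher were the urea cycle enzyme CPS1 (7.49-fold), GPNMB (6.16-fold), the WNT inhibitor WIF1 (5.47-fold), TSPAN7 (4.86-fold), TAGLN (4.83-fold), ABCC2 (4.80-fold), SLC2A3 (4.78-fold) and NDNF (4.31-fold), with the collagen COL8A1 at least 18.9-fold higher. Lower genes included CLMP (18.7-fold), CXCL14 (11.3-fold), the chemokine receptor CXCR4 (9.95-fold), SFRP1 (9.89-fold), CXCL1 (8.86-fold), TMCC3 (8.09-fold), STC1 (7.92-fold), TNC (6.38-fold) and the integrin ITGA2 (5.90-fold). CEMIP was at least 28.7-fold and CHI3L1 at least 18.2-fold lower.

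With the combination, 14 of the 29 lists lay outside the range of random lists. Inflammatory and NF-kB genes were lowest, with a median of -1.36 over 20 genes (random lists, -0.14 to 0.14), 12 of them at least 2-fold lower, among them CXCL3 (-2.49). Across the settings tried, the median of this list ran from -1.41 to -0.60. Cell cycle arrest genes had a median of -0.56 (GDF15 at -1.51, DDB2 at -1.42), PI3K-FOXO feedback genes -0.44 (PDK4 at -1.48), immediate early genes -0.36 with 8 of 25 at least 2-fold lower (DUSP5 at least 3.23-fold, PHLDA1 at -2.05), mesenchymal genes -0.25, apoptosis regulators -0.17, the unfolded protein response -0.16, prostate stem and progenitor markers -0.15 and the interferon response -0.13. G2-M and mitosis genes were higher by a median of 0.39, with 36 of 38 above 0 and 0 at least 2-fold higher, WNT and TGF-beta targets by 0.28, sterol and fatty acid synthesis by 0.23, G1-S and DNA replication by 0.17 and tubulins by 0.14. The medians of the apoptosis, prostate stem, interferon, G1-S and tubulin lists lay inside the range of random lists under at least 1 alternative setting. Inside the range in the main analysis were oxidative phosphorylation (-0.06), androgen signalling (-0.12), glycolysis and hypoxia (-0.05), ribosomal proteins (-0.02), ribosome biogenesis (-0.03), Notch and Hedgehog (-0.04), epithelial genes (-0.01), drug efflux transporters (-0.03), housekeeping (0.01), autophagy and lysosome (0.01), keratinised squamous epithelium (0.10), heat shock (0.10), the amino acid and ATF4 response (0.07), MHC class I (0.12) and fibroblast and matrix genes (0.17), the last of which lay outside it under 1 alternative setting.

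The combination was also set against each single drug. Against taxotere, 174 genes were at least 2-fold higher and 126 lower in the combination (2.98%). Fibroblast and matrix genes were higher there by a median of 1.15, with 6 of 10 at least 2-fold higher, cell cycle arrest genes by 0.48 and mesenchymal genes by 0.40. Inflammatory and NF-kB genes were lower by a median of -0.64, with 7 of 20 at least 2-fold lower. Against NVP-BEZ235, 825 genes were higher and 504 lower in the combination (13.2%). Interferon response genes were higher by a median of 1.33, with 21 of 32 at least 2-fold higher, and WNT and TGF-beta targets by 1.23, whereas G2-M and mitosis genes were lower by -0.72 and inflammatory genes by -0.86. PI3K-FOXO feedback genes had medians of -0.03 against taxotere and 0.01 against NVP-BEZ235, both inside the range of random lists. Their lower medians with taxotere (-0.37), NVP-BEZ235 (-0.45) and the combination (-0.44) all share the single vehicle array. A vehicle array that stands apart for these genes therefore cannot be told apart from a shift common to the treatments.

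Each drug's difference could be read from a pair of comparisons that share no array. For taxotere, these are taxotere minus vehicle and the combination minus NVP-BEZ235. ALDH1A1, AQP4, the glutathione transferase GSTA1, keratin KRT4, the transporter ABCA8, COL8A1, C9orf152, KLRG2, ERP27 and the bile acid conjugating enzyme BAAT were the genes most clearly higher in both. LINC00973, EREG, CEMIP, TNC, DUSP5, the protease PAPPA, CLMP, NT5E, FOSL1 and C11orf96 were the most clearly lower in both. GSTA1 was at log2 8.70 and 8.74 with taxotere and the combination, against 3.34 and 2.51 with vehicle and NVP-BEZ235, and DUSP5 at 3.84 and 3.48 against 7.69 and 8.45. In all, 216 genes were at least 2-fold higher in both differences, where independent lists of these sizes would share 28.2, and 124 were lower in both, against 15.2. In opposite directions, 10 genes were higher without and lower with NVP-BEZ235, against 17.2, and 42 were lower and then higher, against 24.8. The differences correlated at Pearson r = 0.423 (Spearman rho = 0.246) across genes. The combination minus NVP-BEZ235 rests on the NVP-BEZ235 array, where 455 genes were at least 2-fold lower than on every other array. Such a gene can count as higher in both although the combination does not exceed vehicle. HP did so, at log2 9.13 in vehicle, 10.59 with taxotere, 3.89 with NVP-BEZ235 and 8.06 with the combination. SFTPB did so too, at 12.8, 14.3, 10.6 and 12.7 on the same arrays, and MUC5B came close, at 8.12, 9.51, 2.70 and 8.15. How many of the 216 genes are of this kind was not counted. The 216 therefore cannot be read as genes that also exceed vehicle with the combination.

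For NVP-BEZ235, the corresponding differences are NVP-BEZ235 minus vehicle and the combination minus taxotere. They correlated at r = 0.0704 (rho = -0.0111). The basement membrane protein NID1 (log2 7.10 and 6.34 without, 9.49 and 8.64 with the inhibitor), EFNB2, CLDN2, PLEKHG4, HKDC1, CRISPLD2, THBD, PLAU, BNC1 and RUNX2 were the genes most clearly higher in both. CHI3L1, haptoglobin HP, CCL20, IGFBP5, the collagenase MMP1, SCGB3A2, DEGS2, CXCL17, TCIM and SLC60A1 were lower in both. The counts were 28 genes higher in both differences, against 7.64 of independent lists, and 65 lower in both, against 8.01. Opposite directions also exceeded independent lists, with 16 genes higher without and lower with taxotere, against 5.53, and 39 lower and then higher, against 11.1.

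**Figure D3:**
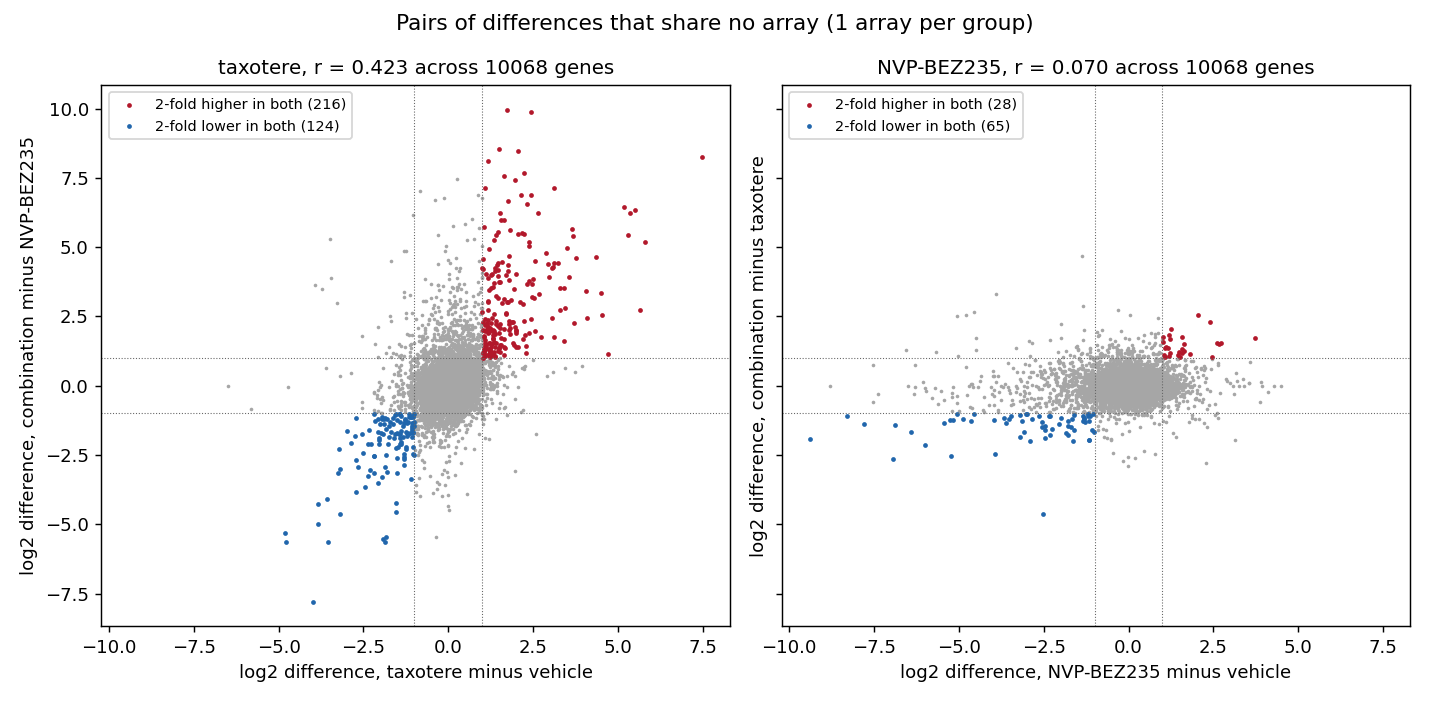
Log2 differences of 10068 genes in a pair of comparisons that share no array, for taxotere (left, taxotere minus vehicle on the x axis, combination minus NVP-BEZ235 on the y axis) and for NVP-BEZ235 (right, NVP-BEZ235 minus vehicle on the x axis, combination minus taxotere on the y axis), 1 point per gene. Dotted lines mark 2-fold differences, and 216 and 124 genes are at least 2-fold higher or lower in both taxotere differences against 28 and 65 for NVP-BEZ235.

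The departure of the combination from the sum of the single drugs on the log2 scale was at least 2-fold upward for 784 genes and downward for 628. CXCL14, WIF1, SPOCK2, SCGB3A2, RAB25 and MFAP5 departed upward, and since each was under log2 4 on the NVP-BEZ235 array and at or above 6 on the other arrays, no size is given for them. Downward departures were those of S100A8 (-5.08), embryonic globin HBE1 (-5.05) and TMCC3 (-3.79), and, without a size because an array was under log2 6, CA12, CEMIP and RAMP1. As 4 arrays enter each departure, its measurement error is larger than that of a difference between a pair of arrays.

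An additive factorial model fitted with limma to all 4 arrays, in which the departure from additivity serves as the error with 1 residual degree of freedom, called 0 genes for taxotere and 0 for NVP-BEZ235 at a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05 it gave 888 and 349 genes, where 503.4 would be reached by chance. ALDH1A1, KRT4, ABCA8 and AQP4, higher with taxotere, and LINC00973, EREG and TNC, lower with it, shared the smallest limma adjusted p for taxotere, 0.220, and each was under log2 6 on at least 1 array. For NVP-BEZ235 the smallest limma adjusted p was 0.993, for genes such as NID1 (log2 effect 2.35) and TCIM (-1.78).

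Taxotere and NVP-BEZ235 alone were also compared with each other through their shared vehicle array. In both, 44 genes were at least 2-fold higher and 76 lower than in vehicle, against 15.1 and 19.3 of independent lists, and 161 genes were 2-fold apart in opposite directions. CDKN1A was lower by 1.61 and 1.52, whereas PLAU was lower by 2.67 with taxotere and higher by 1.57 with NVP-BEZ235. The differences had r = -0.0108 and a covariance of -0.0053 across genes. Simulated arrays with no effect and a shared control gave r = 0.499, a covariance of 0.0619 and an overlap of 3.33 genes. They had a normal error with an SD of 0.249 per array. The observed differences were wider, with an SD of 0.596 for taxotere and 0.821 for NVP-BEZ235. The simulated overlap therefore does not measure how many shared genes come from the vehicle array. With a single vehicle array the control could not be split between the comparisons.

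Further genes were chosen in advance for their bearing on the drugs. The tubulin genes TUBB (log2 13.18 to 13.44) and TUBB3 (12.82 to 13.63) were highly expressed on all 4 arrays, with TUBB3 higher by 0.65 with NVP-BEZ235. The probe sets used for both are of a kind marked as shared between transcripts. The drug efflux pump ABCB1 lay between 3.00 and 3.04 and the stem cell marker PROM1 between 2.38 and 2.42, both under log2 6 on every array. CD44 was at 12.42 in vehicle and 12.21, 12.91 and 12.08 with taxotere, NVP-BEZ235 and the combination. The insulin receptor substrate IRS2 was lower by 0.70, 0.97 and 0.73 than in vehicle, and ERBB3, at 11.93 in vehicle, was lower by 0.72 with NVP-BEZ235. The proliferation marker MKI67 was 2.40-fold higher with NVP-BEZ235, 1.49-fold with taxotere and 1.41-fold with the combination. Its other measured probe sets were higher by 1.07 to 1.57 with NVP-BEZ235, by 0.04 to 0.06 with taxotere and by 0.21 to 0.63 with the combination.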

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

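The tests on the NVP-BEZ235 array in this part were chosen after the values were seen. Among the fixed gene lists, some had medians outside the range of random lists with opposite signs when the same drug was read without and with the other drug. With 1 array per group, none of these differences was tested. For NVP-BEZ235, the interferon response list had a median of -1.69 without taxotere and 0.18 with it, and fibroblast and matrix genes of -0.83 and 1.15. WNT and TGF-beta targets had medians of -0.80 and 0.28, MHC class I genes of -0.58 and 0.23, cell cycle arrest genes of -0.48 and 0.48, and heat shock genes of 0.36 and -0.24. For taxotere, G2-M and mitosis genes had a median of 0.32 without NVP-BEZ235 and -0.72 with it. Interferon response genes had -0.37 and 1.33, fibroblast and matrix genes -0.66 and 0.49, and WNT and TGF-beta targets -0.27 and 1.23.

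The NVP-BEZ235 array enters each of these contrasts and lies at least 2-fold from every other array for 669 genes. Noise of single probe sets is argued against, since 306 of 307 other probe sets of these genes (99.7%) had the same sign, and degraded RNA is argued against for this array, since the ratios of 3' to 5' probe sets of both control genes tested (2 of 2) lay within the range of the other arrays. A response to NVP-BEZ235 that is the same with and without taxotere is also argued against as the source of most of the size of the differences. Over the 1082 genes at least 2-fold from vehicle with NVP-BEZ235, the combination minus taxotere was a median of 0.0209 times as large (quartiles -0.19 and 0.242). The difference that chose these genes also divides the ratio, so a peculiarity of either array pulls the ratio toward 0. The ratio therefore does not speak to a smaller shared response, or to one of part of the genes. In both differences 28 genes were at least 2-fold higher and 65 lower, with 16 and 39 in opposite directions. What stays open includes a response to the inhibitor that taxotere prevents, and a tumour or clone that differs for reasons other than the drug. The latter may fit the 29 genes under log2 4 on this array and at or above 7 on the rest. RAB25 and GRHL2 are among them. A difference in sample preparation other than RNA degradation was not tested and stays open too. These explanations cannot be told apart with 1 array per group.

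Outside the main measurement, a control probe set for 18S ribosomal RNA was 1.44-fold higher on the combination array than on the vehicle array, and lower with taxotere (intensity 368) and NVP-BEZ235 (477) than with vehicle (1225). Another 18S probe set was lower on the combination array than on the vehicle array, at an intensity of 305 against 369. It was at 89 with taxotere and 115 with NVP-BEZ235. A further one was higher with taxotere (477) and NVP-BEZ235 (471) than with vehicle (442). An Alu control was at 556 with vehicle and 807 with the combination, against 322 with taxotere and 349 with NVP-BEZ235. Except for the further 18S probe set, these controls were lower with each single drug than with vehicle and the combination. The departure from additivity divides the arrays in the same way. The cause was not tested. Among 1242 probe sets without a gene name in the annotation used that reached log2 6, 99 were at least 2-fold from vehicle with taxotere, 157 with NVP-BEZ235 and 81 with the combination.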

How the results depend on the processing

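Of 200 repeats of the counts and correlations under other settings, 173 stayed within 1.5 times the main count or 0.1 of the main correlation. With a filter at log2 8, which tests 7941 genes, genes at least 2-fold higher numbered 223 with taxotere, 287 with NVP-BEZ235 and 141 with the combination against vehicle, the combination against taxotere gave 104 higher and 83 lower, 14 genes were higher in both NVP-BEZ235 differences that share no array, and 70 genes overlapped between the single drugs. With a pseudocount of 32, which shrinks differences of low genes by construction, the combination against taxotere gave 107 higher and 81 lower, both NVP-BEZ235 differences 12 higher and 37 lower, and the overlap 71. With the mean of all probe sets, which tests 7537 genes, counts were 203 higher and 180 lower with taxotere, 288 and 408 with NVP-BEZ235, 132 and 127 with the combination, 83 higher and 84 lower in the combination against taxotere, where the main counts have more genes higher than lower, and 489 higher against NVP-BEZ235. The same setting gave 128 higher and 77 lower in both taxotere differences, 12 and 42 in both NVP-BEZ235 differences, 480 and 399 for the departure from additivity, and an overlap of 71. The choice of genes and probe sets without the NVP-BEZ235 array, added after the data were seen, gave 343 higher and 291 lower with taxotere and 230 and 185 with the combination. The limma fit called 0 genes under each setting, with a trend too. List medians kept their side of the random range in 657 of 687 repeats, lost it in 21 and gained it in 9, and 2958 of 3094 differences of named genes moved by less than the SD between probe sets. No paired analysis was possible because each group has 1 array and so at most 1 replicate number to share, and the additive limma fit takes the other drug as a block. Levels under log2 6 limit what can be said of weakly expressed genes.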

Other observations

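The gene lists in this part, and the tests on them, on probe sets and on background, were chosen after the values were seen, whereas the taxotere differences that share no array and their correlation were planned. Genes of oxidant and xenobiotic defence, a group not among the fixed lists, were higher with taxotere. The list of 24 measured genes, known targets of NRF2 and enzymes of xenobiotic metabolism, had a median of 1.05 with taxotere and 0.95 with the combination against vehicle, with 13 and 11 members at least 2-fold higher and 0 lower. With NVP-BEZ235 alone its median was -0.47, 7 members were at least 2-fold lower and 1, OSGIN1, at least 2-fold higher. Besides ALDH1A1, GSTA1, AKR1B10 and CBR3, members higher with taxotere were OSGIN1 (log2 6.10 in vehicle and 8.33 with taxotere), CBR1 (12.21 and 13.87), ALDH3A1 (9.73 and 10.91), AKR1C3 (13.78 and 14.97) and the glutathione synthesis gene GCLM (11.39 and 12.42), while ABCC3 (12.87 and 12.45) and TXNRD1 (14.38 and 14.22) were lower and GCLC (13.43 and 13.43) was level. A hypothesis is that the pathway as a whole was higher with taxotere, beyond the genes already singled out. The 16 measured members in no fixed list and not named by the rule for named genes had a median of 0.96 with taxotere against vehicle (random lists, -0.14 to 0.18) and 0.65 with the combination against NVP-BEZ235 (random lists, -0.28 to 0.18), but the list was chosen after the values were seen, and the 16 include OSGIN1, CBR1, ALDH3A1, AKR1C3 and GCLM, so this does not decide it.

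A list of EGF receptor ligands and transcripts induced by MAP kinase signalling had a median of -1.31 over 19 genes with taxotere and of -1.36 with the combination, with 13 at least 2-fold lower in each. Of the 4 ligands measured, EREG and BTC were at least 2-fold lower with taxotere, while HBEGF (-0.84) and TGFA (0.61) were under 2-fold apart. The phosphatase DUSP6 was at log2 12.57 in vehicle, 10.81 with taxotere, 12.70 with NVP-BEZ235 and 10.83 with the combination, BTC at 7.47, 5.95, 8.85 and 5.70, and IER3 at 12.70, 11.39, 12.83 and 11.47. With NVP-BEZ235 alone the list's median was 0.16, inside the range of random lists. Whether the pathway shifted beyond the genes singled out could not be decided, since 3 of its measured members were in no fixed list and not named by the rule.

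The genes at least 2-fold apart in both taxotere differences, 340 in all, are a pattern shared between differences that have no array in common. A gene that stands apart on the NVP-BEZ235 array can pass the second difference through that array alone. Noise of single probe sets is argued against, since 98.7% of 152 other probe sets of these genes had the same sign in both differences. Values near background stay open for 182 of these genes, which were under log2 6 on at least 1 array, while the other 158 were at or above it on all 4. A response to taxotere is the explanation the design names, and the correlation of 0.423 across genes is consistent with it, but the number of tumours behind each array is not given in the sources used here. With 1 array per group, it cannot be told apart from differences between the tumours sampled.

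Genes of lung epithelium were at high level on all 4 arrays of tumours labelled as a prostate carcinoma line. Of 20 such genes with a probe set, 10 were at or above log2 6 on every array, including NKX2-1, SFTPB, NAPSA, SFTA3 (11.33 to 13.71) and SLC34A2 (8.67 to 13.15). Normal lung tissue in the samples is argued against, since SFTPC and SCGB1A1, abundant in alveolar and airway cells, did not exceed log2 2.68. Cross-hybridisation of single probe sets is argued against for NKX2-1 and SFTPB, whose probe sets were all at or above log2 7.20 on every array, although both of NKX2-1 are of the kinds marked as shared between transcripts, and it stays open for the other 8 genes, each with a single probe set at or above log2 6, including AGER, whose other probe set did not exceed 3.21. Tumour cells other than those the labels name are a possible explanation that stays open as well, because no reference profile of the line was used here.

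The list of lung epithelium genes also differed between arrays, with a median over 14 measured genes of 1.25 with taxotere, -2.09 with NVP-BEZ235 and 0.54 with the combination against vehicle. Within it, SCGB3A2 was at log2 11.29 in vehicle, 13.73 with taxotere, 1.92 with NVP-BEZ235 and 11.80 with the combination, and MUC5B at 8.12, 9.51, 2.70 and 8.15. Of the 14 genes, 8 were at least 2-fold higher with taxotere and 1, LAMP3, was lower by that margin. With NVP-BEZ235, 0 were at least 2-fold higher and 10 lower, and with the combination 2 were higher and 0 lower.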
